A study of Mus musculus with 320 samples.

How the data were processed

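RNA was measured in 320 single cells of the developing mouse cortex (CD1 strain), captured on a Fluidigm C1 microfluidic chip and made into Nextera XT libraries. Groups were read from the sample characteristics, since the titles of all cells begin with the same words. Each title also carries a title number from 1 to 19 and a position number from 1 to 40. Per the labels, the authors aligned reads with TopHat2 2.0.11 to the mm10 genome and counted them per gene with HTSeq 0.6.1. The deposited values are log2 of RPM plus 10, for 15980 genes, where RPM is the reads of a gene scaled to the same library total in each cell. The unit was settled from the values themselves. After back-transformation, all 704401 values above 0 were whole read numbers within a tolerance of 0.001 once each cell's total was found. The listed genes held a median of 71.6% of the reads in E14.5 FlashTag cells, 70.1% in E15.5 FlashTag cells and 72.1% in Kir-Gfp cells, so the RPM scale also counts reads outside the listed genes. How the authors chose the cells and genes is not stated in the labels. Of the gene identifiers, 15897 were found in the GENCODE annotation of the mouse genome, which gave the coordinates, and 12133 of these were protein coding.

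Each deposited sample is 1 cell, and no animal, litter or culture is named. Every group therefore counts as 1 sample, and no test, p-value or standard error was computed between groups. The level of a gene in a group is the mean over cells of the deposited log2 value, and an effect is the difference between 2 such means, with the standard deviation (SD) over cells beside it. The choice of this level over the log2 ratio of mean RPM, or of summed reads, was made after both had been computed, because the deposited unit is log2. Values from both ratios are given as alternatives. Shares of cells have exact (Clopper-Pearson) 95% intervals, which cover counting error only. A count of 0 is given with the share that 3 counts would be. Reads without molecular identifiers are not independent molecules.

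The comparisons, the 33 fixed gene lists and the marker genes were set before the data were examined. So was the rule for naming genes, apart from the measure it ranks by. The rule takes genes with at least 50 RPM and a read in at least 25% of cells in either group, whose direction is the same in the mean log2 value, the mean RPM, the summed reads and the share of cells with a read. Of these it names the 10 highest and the 10 lowest, and in addition 2 to 4 members of each list with the largest differences. As first set, the rule ranked by the log2 ratio of group levels. Ranking by the difference of mean log2 values, and asking for its direction, followed the later choice of level. A few genes that the rule names are not reported here. Ribosomal protein pseudogenes, predicted genes and sex markers (Xist, Tsix and Y-linked genes) are left out of the ranking and described separately. A list member counted as measured at 10 RPM in either group, and as higher or lower when its difference passed 0.58, the log2 of 1.5, on the log2(RPM + 10) scale, where a 1.5-fold difference in RPM appears smaller. For each of the 23 lists with at least 3 measured members, the median difference was set against 10000 random lists of the same size matched on mean level. Random lists take genes one by one and ignore that members of a list vary together, so the ranges are too narrow for co-expressed lists.

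Cells were clustered once over all groups with scanpy 1.11.5 and the Leiden method of igraph 0.11.9 on 2000 variable genes with reads in at least 32 cells, without cell cycle, ribosomal, mitochondrial and sex genes (15 principal components, 15 neighbours, Leiden resolution 1). The number of variable genes and the minimum of cells were settled after several settings had been looked at. A cluster was named when at least 3 markers of a class were read in at least 25% of its cells and lay 0.5 above the other cells, at least 2 times as many as for any other class, with at least 1 among the 10 top genes and no other class having more there. This naming rule was made stricter after the first clusters had been seen. No doublet caller was run. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

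Alternatives were the log2 ratio of mean RPM, offsets of 1 and 50 RPM, centring on the median difference of genes with at least 50 RPM, cells with at least 1000 genes and 50000 reads, and cells thinned to 208969 reads. The thinned set leaves out cells with fewer reads (19 E14.5 FlashTag, 9 E15.5 FlashTag and 4 Kir-Gfp cells), so it changes the cells as well as the depth. Others were leaving out each title number in turn, leaving out for each gene the cell with most reads of it, cells typed female, single cell classes, classes weighted equally, other minimum levels for list members, and other clustering settings. The ratio of summed reads, differences within title numbers, and the omission of neuron-like cells or of cells whose markers rank highest for neurons were added after seeing the data. Summed reads had been planned as the level for the case of count files. TMM factors and median-of-ratios size factors, planned for the case of count files, were not run, because the deposited unit is log2. The pipeline was tested on simulated cells, with known folds put on genes picked at random. Each gene was drawn independently, from its mean and spread over E14.5 FlashTag cells and the read totals of the real cells. Co-expression, cell classes and title numbers were not simulated, so the values below do not cover them. A true 2-fold difference appeared as a median of 0.33 for E15.5 against E14.5, 0.32 for Kir-Gfp against E14.5 and 0.31 for Kir-Gfp against E15.5, and 90%, 84% and 74% of such genes had the right direction. A simulated list of 20 genes with a 2-fold difference lay at percentiles 100, 99.97 and 99.88 of the random lists.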

Results

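The series holds 320 single cells from the embryonic mouse cortex in 3 groups. FlashTag is a dye injected into the ventricle that marks cells dividing at the ventricular surface, so labelled cells of a group share a birth date. Cells given the developmental age of embryonic day E14.5 (E14.5 FlashTag) made up 32.8% of the 320. Those given the age E15.5 (E15.5 FlashTag) made up 50.6%, and 53 E14.5 cells carrying a plasmid for Kir2.1 and GFP (E14.5 Kir-Gfp) 16.6%. Kir2.1 is an inwardly rectifying potassium channel whose overexpression makes the membrane potential more negative. Per the series description, the Kir2.1 plasmid was electroporated at E14.5 and a GFP plasmid at E15.5, and FlashTag followed by 12 h. No electroporation or delay is stated for the E14.5 FlashTag cells, so no group is an electroporated control of the same age as the Kir-Gfp cells. Kcnj2, the gene that encodes Kir2.1, and Gfp are not among the 15980 genes used here, so the Kir-Gfp label was not checked against its own transcript.

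E14.5 FlashTag cells had a median of 369033 reads per cell (range 14692 to 1408117), E15.5 FlashTag cells 486535 (39956 to 3118179) and Kir-Gfp cells 541062 (30251 to 1222713). The median number of genes with a read was 1787, 2384 and 2104 in the same order. Of all values, 86.2% were at 0 reads. E14.5 FlashTag and Kir-Gfp cells both used title numbers 1 to 10, and E15.5 FlashTag cells used title numbers 11 to 19. No title number held cells of both ages.

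**Figure D1:**
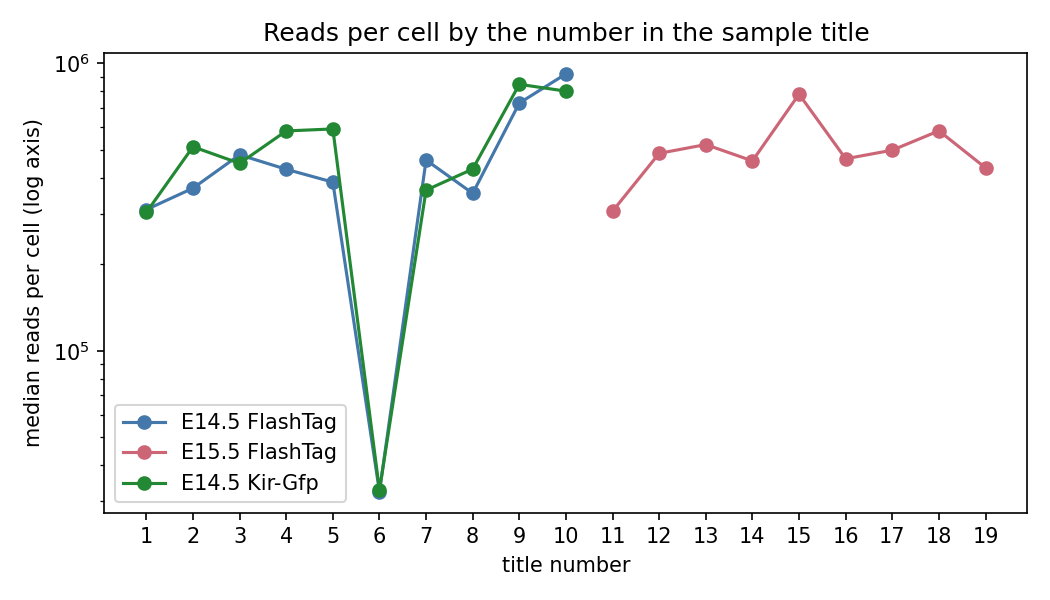
Median reads per cell (log axis) by title number for the 3 groups, each point being the cells of 1 group under 1 title number. Title number 6 was the shallowest in both groups that used it, at 32384.5 reads for E14.5 FlashTag and 32807 for Kir-Gfp.

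The first comparison asks which cell classes the labelled cells fell into. Apical progenitor-like cells, marked by Vim, Fabp7, Slc1a3, Sox2 and Pax6, made up 18 E14.5 FlashTag cells (17.1% of the group, interval 10.5 to 25.7), 32 E15.5 FlashTag cells (19.8%, 13.9 to 26.7) and 11 Kir-Gfp cells (20.8%, 10.8 to 34.1). Basal progenitor-like cells, marked by Btg2, Sstr2, Gadd45g, Elavl4 and Igsf8, made up 6.67% (2.72 to 13.3), 6.17% (3.00 to 11.1) and 9.43% (3.13 to 20.7). The listed markers Eomes, Neurog1, Neurog2 and Insm1 did not pass for this cluster, while 2 neuron markers did. Of the class, only Igsf8 was among its 10 top genes. Neuron-like cells, marked by Neurod2, Neurod6, Tubb3 and Dcx, made up 14.3% (8.22 to 22.5), 13.0% (8.21 to 19.1) and 9.43% (3.13 to 20.7). The intervals of the 3 groups overlapped in each class with a name. Clusters without a name held 61.9%, 61.1% and 60.4% of cells, but were unevenly spread. A cluster with Gadd45g among its top genes held 16 E14.5 FlashTag, 25 E15.5 FlashTag and 1 Kir-Gfp cells, and a cluster with Nfix among its top genes 5, 22 and 1, both singled out after their counts were seen. The apical progenitor-like share depended on the clustering. An unnamed cluster of 52 cells had Neurod6 as its top gene. By the mean rank of their markers, 47 E14.5 FlashTag, 60 E15.5 FlashTag and 19 Kir-Gfp cells ranked highest for neurons. In the same order 40, 65 and 26 cells ranked highest for basal progenitors, and 17, 37 and 8 for apical progenitors. The shares of named clusters are therefore not shares of these cell types.

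The comparison of E15.5 with E14.5 FlashTag cells asks how these groups differ. The time between their birth dates is not known, since a delay to labelling is stated for E15.5 but not for E14.5 FlashTag cells. Zbtb20 (ENSMUSG00000022708, chromosome 16, 42875881 to 43642602, plus strand), a zinc finger gene of late progenitors and astrocytes, was 1.94 higher at E15.5. Its mean was 6.75 (SD 2.70 over cells) against 4.81 (SD 2.36), and it had a read in 91.4% (85.9 to 95.2) against 48.6% (38.7 to 58.5) of cells. Slc1a3 (ENSMUSG00000005360, chromosome 15, 8634124 to 8710764, minus strand), a glutamate transporter of radial glia, was 0.96 higher (5.31, SD 2.55, against 4.34, SD 2.16). A read of Slc1a3 was found in 67.9% (60.12 to 75.01) against 35.2% (26.2 to 45.2) of cells. Dbi was 0.92 higher, Nfix 0.90 higher and Fabp7 0.83 higher, and all are expressed by late radial glia. With classes weighted equally the Nfix difference was -0.037, but it kept its sign within apical progenitor-like, neuron-like and unnamed cells. Equal weights give the basal progenitor-like class, with 7 E14.5 and 10 E15.5 cells, as much weight as the larger classes.

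Among genes of general function, Ccrn4l was 1.45 higher at E15.5, Ube2r2 1.23, Ddx5 1.11, Map1lc3b 1.09, Ift46 0.99, Srp14 0.97 and Zranb1 0.92. The lowest were Shfm1 at -1.24 (5.59, SD 2.63, against 6.82, SD 2.88), Sos2 at -0.92, Snrnp27 at -0.91, Zmynd11 at -0.90 and Dnttip2 at -0.85. Nasp, a histone chaperone of S phase, was at -0.81, the upper-layer transcription factor Pou3f3 at -0.79, Brcc3 at -0.76, and the axon guidance receptor Nrp1 and the ribosomal gene Rplp1 both at -0.75. Without title number 1 Pou3f3 was at -0.52, and within neuron-like cells Rplp1 was 0.18 higher. Ezh2, a Polycomb gene of early progenitors, was at -0.88 (6.31 against 7.19). The basal progenitor gene Eomes was 0.83 higher and Dcx, of migrating neurons, 0.67 higher, while Neurod6 was at -0.69. Within neuron-like cells both neuronal genes had the opposite sign, Dcx at -0.34 and Neurod6 at 0.25. Without title number 5 Dcx was 0.44 higher, and without title number 9 Neurod6 was at -0.43. Each of these differences was smaller than the SD over cells.

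The late apical progenitor identity list was higher at E15.5, with a median of 0.42 over 16 measured genes, 6 of them higher and 0 lower. Matched random lists gave -0.09 to 0.22. The p53 target list was also above its range, with a median of 0.21 (percentile 99.7), but 0 of its 10 measured genes passed 0.58 on the log2(RPM + 10) scale, where low levels compress a difference. By the log2 ratio of mean RPM, Ccng1 was at 1.77, Cdkn1a at 1.62 and Bax at 0.73. Mdm2 was at 0.33, Ccng1 at 0.32 and Bax at 0.30, and Mdm2 was at 0.51 without title number 1 and at -0.40 with summed reads. Below their ranges lay the G2/M list at -0.10 (percentile 0.00), the G1/S list at -0.044 (1.67) and the mitochondrially encoded list at -0.26 (0.355), in which 3 of 11 measured genes were lower by over 0.58. In this list mt-Co2 was at -0.76 (-0.50 without title number 1) and mt-Cytb at -0.71. The gene mt-Co1 was 0.34 higher (0.23 without title number 1 and 0.53 without title number 2). Top2a was at -0.37 in the G2/M list, but Mki67 was 0.31 higher. The G2/M list lay inside its range with the log2 ratio of mean RPM (percentile 2.67). Its median was -0.013 in female cells, and it had the opposite sign within neuron-like cells (0.010) and with members of at least 50 RPM (0.0041). Within apical progenitor-like and within neuron-like cells the G1/S median had the opposite sign, at 0.092 and 0.023. Within apical progenitor-like cells the mitochondrially encoded median was -0.083 (percentile 67.6) and the p53 target median 0.20 (92.7), both inside their ranges. Without title number 1 the mitochondrially encoded median was -0.14, and without title number 7 the G2/M median was -0.030.

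The other 18 lists lay inside their ranges at E15.5 against E14.5. Their medians were 0.18 for apical progenitor, 0.078 for basal progenitor, -0.073 for pan-neuronal, -0.017 for deep-layer and 0.054 for upper-layer neuron identity. The early apical progenitor list was at -0.084, Wnt signalling at -0.015, Notch signalling at 0.088, potassium channels at 0.14, and sodium and calcium channels at 0.0098. Immediate early genes were at -0.044, heat shock and stress at -0.037, interferon response at -0.055, glycolysis and hypoxia at 0.026, and ribosomal proteins at -0.025. Neuron migration and axon guidance was at -0.042, synapse and neurotransmitter receptors at 0.12, and dorsal telencephalon at 0.11. Leaving out 1 title number turned the sign of several of these medians, among them basal progenitor (-0.014 without title number 14) and neuron migration (0.047 without title number 19).

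**Figure D2:**
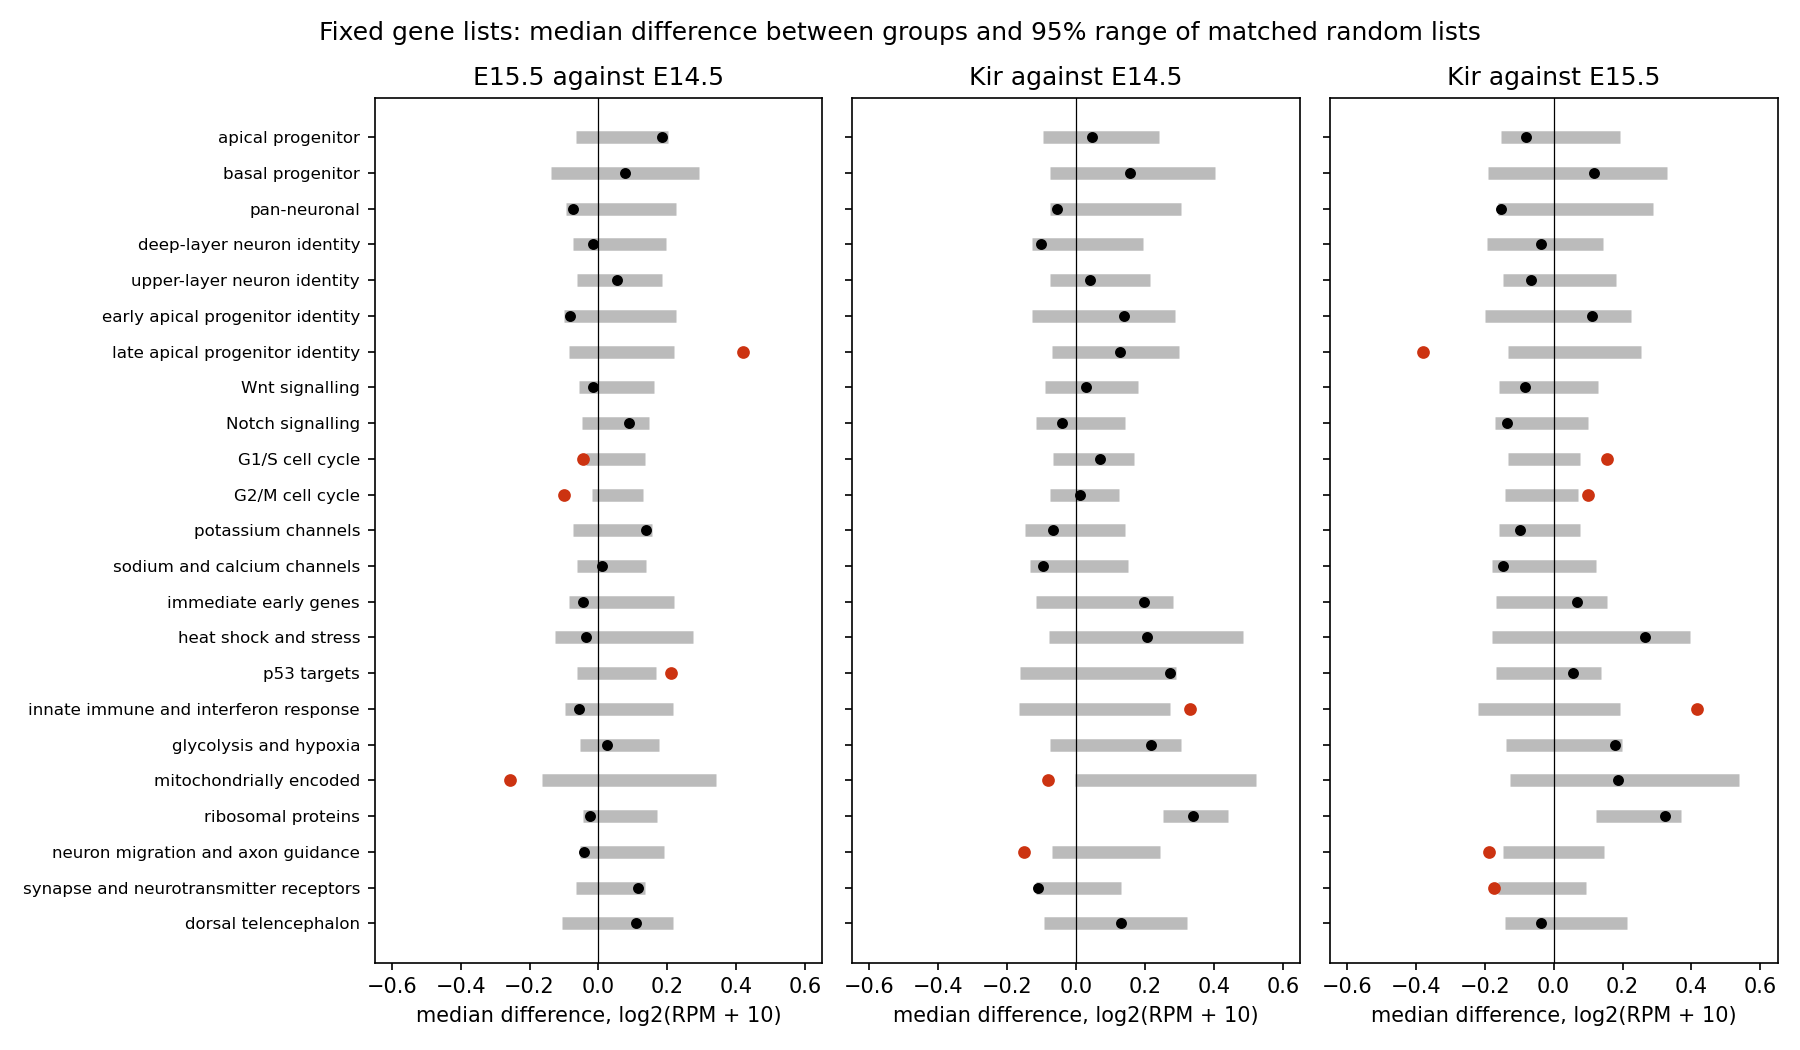
Median difference (log2) of each fixed gene list in the 3 comparisons, with the 95% range of 10000 matched random lists. The late apical progenitor list stands above its range at E15.5 against E14.5 (0.42) and below it in Kir-Gfp against E15.5 (-0.38).

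The comparison of Kir-Gfp with E14.5 FlashTag cells asks how cells carrying the Kir2.1 plasmid differ from E14.5 FlashTag cells, for which no electroporation is stated, so Kir2.1 is not separated from electroporation or from the time of labelling. Tubb3 (ENSMUSG00000062380), the neuronal beta-tubulin, was the lowest named gene at -1.19 (4.52, SD 2.21, against 5.71, SD 2.95), with a read in 50.9% against 62.9% of cells. Pax6, a progenitor transcription factor, was 1.22 higher (6.19, SD 2.86, against 4.98, SD 2.45), and the replication gene Mcm6 was 1.10 higher (4.73 against 3.63). The highest were Cox7c at 1.54 (7.87, SD 2.32, against 6.33, SD 2.70), Sumo3 at 1.498, Atp5o at 1.48, Tsn at 1.44 and Hsp90ab1 at 1.41. Hsp90ab1 was at -0.032 within apical progenitor-like cells. Ddx52 followed at 1.40, Cox5b, Syf2 and Ezr at 1.35, and Cct8 at 1.34. Among these, Cox7c, Atp5o and Cox5b encode parts of the respiratory chain and ATP synthase.

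After Tubb3, the lowest genes in Kir-Gfp cells were Rsrc2 at -1.09, Dek at -1.07, the immediate early gene Ier2 at -1.03, Myeov2 at -1.01, Capzb at -0.93, Eif3e at -0.91, Ccdc23 at -0.90, Iscu at -0.87 and Pigp at -0.80. Ccdc23 was at -0.57 without title number 2, and Pigp at -0.51 without title number 6. The median difference of the 2441 genes that met the level and detection minimum in this comparison was 0.16, against 0.13 for E15.5 against E14.5 and -0.0057 for Kir-Gfp against E15.5. Ribosomal protein genes had a median of 0.34, with 23 of 82 higher, and this lay inside the range of matched random lists (percentile 43.1).

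The neuron migration and axon guidance list was lower in Kir-Gfp cells, with a median of -0.15 over 19 measured genes, 0 of them higher and 3 lower. Matched random lists gave -0.07 to 0.24. Nrp1 and the ephrin receptor Epha5 were both at -0.71, while Epha4 was 0.51 higher. Nrp1 had the opposite sign within apical progenitor-like cells (0.84) and without cells ranked neuron (0.015). Nrp1 and Dcx, both in this list, are also among the neuron markers of that ranking, so a change there may be partly built in. Epha5 was at -0.42 without title number 4, and Epha4 at 0.11 without title number 9 and 0.78 without title number 4. Without title number 7 the list median was -0.069, and without title number 4 it was -0.080. It was 0.011, inside the range, without the 47 E14.5 FlashTag and 19 Kir-Gfp cells whose markers ranked highest for neurons, and inside its range at percentile 31.9 within apical progenitor-like cells and 2.95 with the log2 ratio of mean RPM. The interferon response list was above its range with a median of 0.33 (percentile 99.1) over 7 measured genes of its 19, with 3 higher and 0 lower. H2-D1 was at 0.80, H2-K1 at 0.68, Ifitm3 at 0.60 and B2m at 0.33. Without title number 9 H2-K1 was at 0.38 and Ifitm3 at 0.17. The list median was 0.17 without title number 9, 0.51 without title number 5, 0.27 after thinning and 0.30 within apical progenitor-like cells, the last 2 of these inside their ranges. The mitochondrially encoded list was at -0.082 where matched random lists centred on 0.27 (percentile 0.470), and it was 0.030 without title number 1. Compared within title numbers it was -0.030, and within apical progenitor-like cells 0.24, both inside their ranges (percentiles 3.63 and 77.2).

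For the Wnt signalling list, the Kir-Gfp cells had a median of 0.030 against E14.5 FlashTag cells (percentile 41), with Wnt7b at -0.59 and Fzd3 at 0.42 (0.27 without title number 4). Apical progenitor genes were at 0.047, basal progenitor at 0.16, late apical progenitor at 0.13, early apical progenitor at 0.14 and dorsal telencephalon at 0.13. Pan-neuronal genes were at -0.056, deep-layer identity at -0.10, upper-layer identity at 0.040 and synapse genes at -0.11. Late apical progenitor was at 0.010 without title number 5, and deep-layer identity at -0.015 without title number 8. Notch signalling was at -0.040, G1/S at 0.069, G2/M at 0.010, potassium channels at -0.067, and sodium and calcium channels at -0.097. Immediate early genes were at 0.20, heat shock and stress at 0.21, p53 targets at 0.27, and glycolysis and hypoxia at 0.22. Without title number 4 the medians were 0.0084 for glycolysis and hypoxia, 0.072 for heat shock and stress and 0.43 for p53 targets, and without title number 6 immediate early genes were at 0.051. Several medians nearer 0 changed sign without 1 title number, among them Wnt signalling (-0.063 without title number 9). Over all cells each of these lists lay inside its range, and centring on the median difference turned the sign of those between 0 and 0.10.

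The comparison of Kir-Gfp with E15.5 FlashTag cells sets the Kir-Gfp cells beside cells with a stated age 1 day later. These groups shared no title number and differed in plasmid. Age, Kir2.1, capture plate and embryos can therefore not be told apart in any difference between them. Zbtb20 was at -1.87 (4.88, SD 2.27, against 6.75, SD 2.70), with a read in 49.1% of Kir-Gfp cells, close to the 48.6% of E14.5 FlashTag cells. Nfix, a transcription factor of late radial glia, was at -1.41 (5.03 against 6.44), Bcan at -0.79 and Dbi at -0.62, though Dbi was 0.22 higher with summed reads. Ezh2 was 1.52 higher in Kir-Gfp cells (7.83 against 6.31) and Nasp 1.48 higher (7.05 against 5.58). Among the other highest genes were Rbx1 at 1.64, Shfm1 at 1.56, Atp5o at 1.55, Cox7c at 1.33, Rpl31 at 1.32 and Gtf2e2 at 1.26. The other lowest were Ccrn4l at -1.93, Rab2b at -1.50, Ddx5 at -1.48, Ube2r2 and Rab11b at -1.25, Cirbp at -1.22, Rsrc2 at -1.17 and Ubap2l at -1.16. Within apical progenitor-like cells Rab11b was at 0.092.

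The late apical progenitor list was lower in Kir-Gfp than in E15.5 FlashTag cells, with a median of -0.38 over 16 measured genes, 0 higher and 4 lower (percentile 0.00). The G1/S list was higher at 0.16 (percentile 99.95), as was the G2/M list at 0.10 (99.3) and the interferon response list at 0.42 (99.99), the last over 7 measured genes. Neuron migration and axon guidance was lower at -0.19 (percentile 0.350), with Dcx at -0.61 (0.068 with classes weighted equally) and Epha5 at -0.58 (-0.31 without title number 4), and synapse and neurotransmitter receptors at -0.17 (1.44), with Gria2 at -0.57. The synapse list lay inside its range after thinning (percentile 3.03) and within apical progenitor-like cells (30.3), and the migration list with the log2 ratio of mean RPM (16.1) and within apical progenitor-like cells (6.43). Without title number 4 the G1/S median was 0.082, and without title number 10 the G2/M median was 0.015. The other 17 lists lay inside their ranges. Of the 69 list medians in the 3 comparisons, 14 lay outside the 95% range of random lists, against 3.45 if the ranges were exact. The ranges are too narrow for co-expressed lists, so more than 3.45 could lie outside by chance. Lists that share genes or cells are also not independent.

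**Figure D3:**
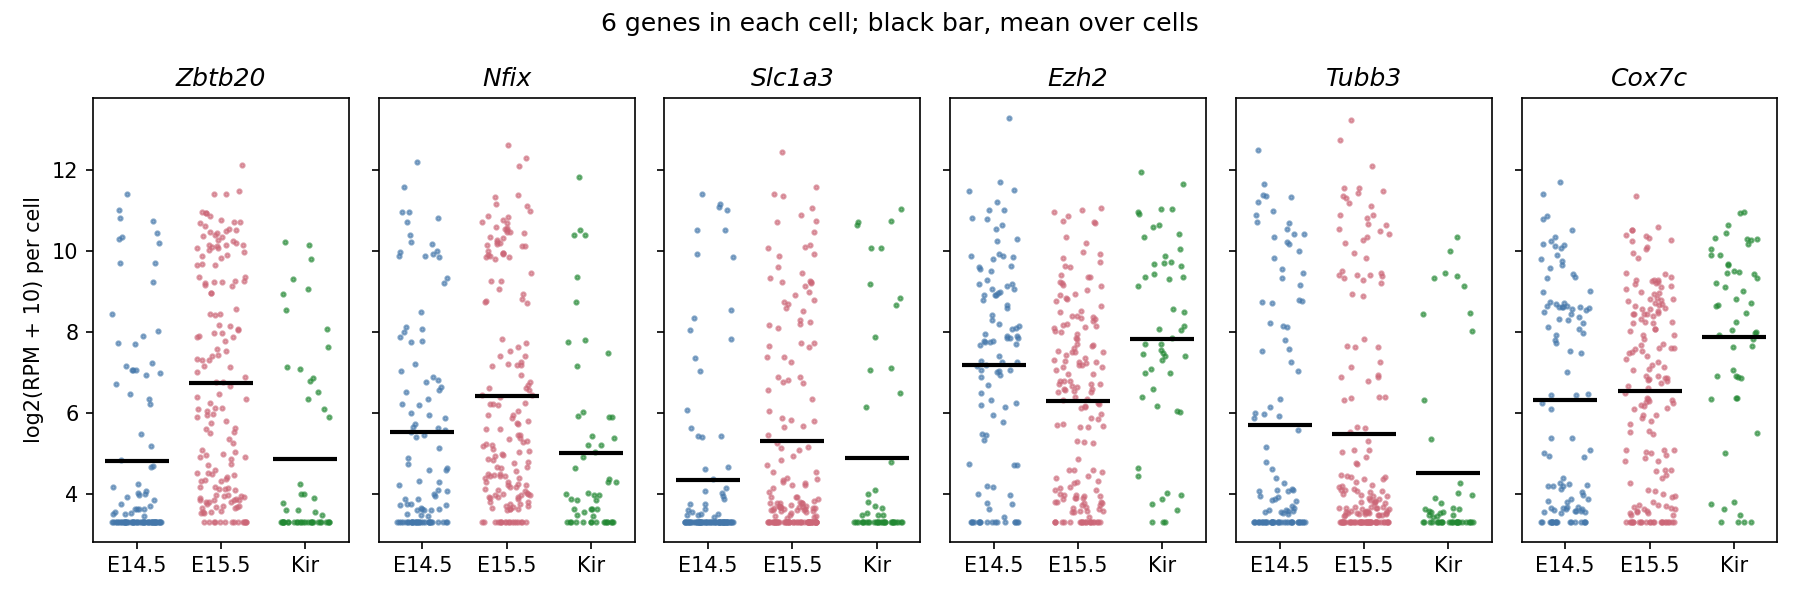
Values of 6 genes as log2(RPM + 10), each point being 1 cell of E14.5 FlashTag, E15.5 FlashTag or Kir-Gfp and each black bar the mean over cells. The mean of Zbtb20 is 4.81, 6.75 and 4.88 in that order.

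The last comparison asks whether Kir-Gfp cells lie towards the E15.5 profile across genes. Over 4465 genes with at least 50 RPM in any group, the Kir-Gfp and E15.5 differences from E14.5 had a correlation of 0.31 when the same E14.5 cells served in both. Using the same cells in both differences creates a correlation by itself. With separate E14.5 cells for each difference the correlation was -0.0030 one way round and -0.091 the other, with a mean of -0.047. Draws of 53 E14.5 FlashTag cells in place of the Kir-Gfp group gave 0.0012 (-0.035 to 0.042). The draws left fewer E14.5 cells for the differences, and split them at random and not by title number. This range, which -0.091 lies outside, is therefore not a like measure for the values above. With the log2 ratio of mean RPM the values were 0.051 and 0.042, with summed reads 0.051 and 0.036, and with the E14.5 cells split by position number -0.066 and 0.036, so the sign depended on the measure and the split. The covariance with shared cells was 0.0289, and the variance of the E14.5 cells alone accounts for 0.0312. These are correlations across genes, which are not independent replicates.

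The E15.5 difference itself was weakly repeatable, with a correlation of 0.13 between odd and even title numbers, and that of Kir-Gfp cells was 0.059. The 50 genes highest at E15.5 on odd title numbers (mean 1.19) had a mean of 0.22 on even title numbers and 0.086 in Kir-Gfp cells, where 30 of 50 were higher. The 50 lowest (mean -0.94) had a mean of -0.24 on even title numbers and 0.15 in Kir-Gfp cells, where 19 of 50 were lower. Over all 4465 genes the mean was 0.062 on even title numbers and 0.067 in Kir-Gfp cells, so the 50 highest lay near the average gene in Kir-Gfp cells. A displacement of Kir-Gfp cells towards the E15.5 profile was not detectable with these cells.

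**Figure D4:**
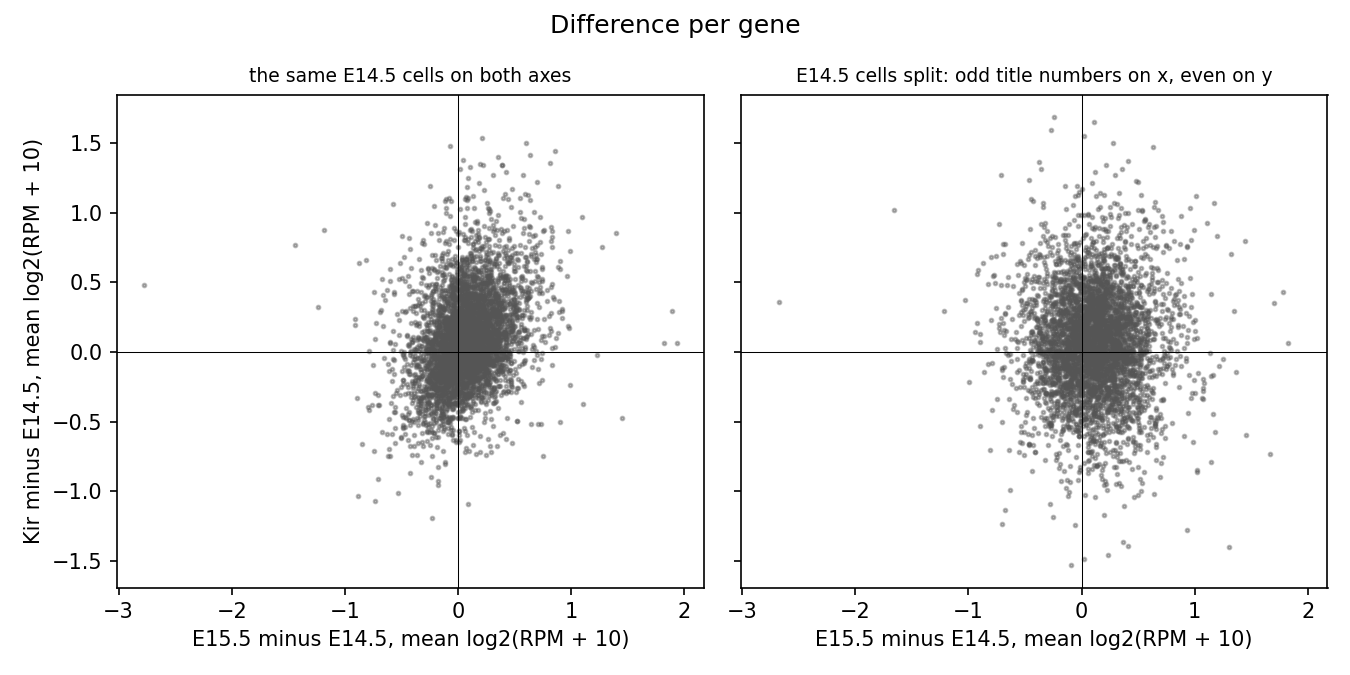
Difference of each of 4465 genes on the log2(RPM + 10) scale, E15.5 minus E14.5 FlashTag on the horizontal and Kir-Gfp minus E14.5 FlashTag on the vertical axis, with the same E14.5 cells on both axes (left) or odd title numbers on 1 axis and even on the other (right). The correlation is 0.31 on the left and -0.0030 on the right.

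Lists of other cell types had at most 2 measured genes and no list median. Gad2, an interneuron gene, had a mean of 1.36 RPM in E14.5 FlashTag, 0.977 in E15.5 FlashTag and 0.907 in Kir-Gfp cells. Maf, of the same list, had a read in 2.86%, 5.56% and 1.89% of cells, and Gad2, which the ventral telencephalon list also holds, in 8.57%, 15.4% and 13.2%. Of the Cajal-Retzius list, Reln had a read in 3.81%, 1.23% and 3.77% of cells. The erythroid genes Hba-a1, Hbb-bs and Alas2 had a read in 0 of 320 cells, which allows a share of cells with a read of up to 0.938%. The microglial genes Tyrobp, Csf1r and Cx3cr1 had a read in 4.32%, 1.85% and 0.617% of E15.5 cells. The oligodendrocyte precursor gene Olig2 had 3.95 RPM at E15.5, and the mural gene Pdgfrb had at most 8.55 RPM, in E14.5 FlashTag cells. The endothelial gene Pecam1 had 6.03, 9.05 and 3.58 RPM and a read in 37.1%, 51.2% and 37.7% of cells.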

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

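No paired analysis was possible between animals, because none is named, but title numbers served as a block for Kir-Gfp against E14.5. The ratio of summed reads, the differences within title numbers, the omission of neuron-like cells or of cells ranked neuron, and the thinned-read correlation were chosen after the result was seen. A list median counted as moved when it shifted by over 50% of the width of its random range, a gene when it shifted by over 0.58, a correlation by over 0.1, and a share when it left its interval. Reversal was counted only for list medians outside their ranges and for gene differences of at least 0.58 in the analysis reported. Of 448 alternative values for the 14 medians outside their ranges, 399 stayed within these limits, 41 moved and 8 reversed. Over all 69 list medians, 205 of 2153 alternative values had the other sign, in 46 of the 69, and 4 of these 46 were among the 14. For 219 named gene differences 6054 of 6450 values stayed, 377 moved and 19 reversed, while 81 had the other sign, and for shares of cells with a read 94 of 120 stayed and 26 moved. A ratio of means has a wider scale than a difference of mean logs, so a larger size there is part of its construction. Otherwise the cause was not tested. Below, lists are named by their first words.

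With the log2 ratio of mean RPM, E15.5 against E14.5 gave late apical progenitor 0.72, G1/S -0.73, G2/M -0.39, p53 0.96 and mitochondrially encoded -0.58. Kir-Gfp against E14.5 gave interferon 1.13 and migration -0.43. Kir-Gfp against E15.5 gave late apical progenitor -0.65, G1/S 0.48, G2/M 0.55, interferon 1.18 and synapse -1.34, and the shared-cell correlation was 0.486. Of these, the G2/M median of E15.5 against E14.5 (percentile 2.67) and the migration median of Kir-Gfp against E14.5 (2.95) lay inside their random ranges. With summed reads, E15.5 against E14.5 gave G1/S -0.64, G2/M -0.59 and p53 0.98, and Kir-Gfp against E14.5 gave interferon 1.46 and migration -0.39. Kir-Gfp against E15.5 then gave late apical progenitor -0.64, G1/S 0.92, G2/M 0.50, interferon 1.60, migration -0.34, synapse -1.03 and Dbi, reversed, 0.22. The shared-cell correlation was 0.496. With an offset of 1, late apical progenitor was 0.88 and p53 0.50 for E15.5 against E14.5, and interferon 0.71 for Kir-Gfp against E14.5. For Kir-Gfp against E15.5 it gave late apical progenitor -0.66, interferon 0.77, migration -0.46 and synapse -0.32. With an offset of 50, late apical progenitor was 0.24 for E15.5 against E14.5.

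The apical progenitor-like class held 18 E14.5 FlashTag, 32 E15.5 FlashTag and 11 Kir-Gfp cells. Within these cells, E15.5 against E14.5 gave G1/S 0.092 and Hsp90ab1 -1.49 (0.64 over all cells), both reversed, and G2/M -0.21. Kir-Gfp against E14.5 gave reversed values for mitochondrially encoded 0.24, Hsp90ab1 -0.032, Eomes -0.16, Nrp1 0.84, Rpl32 -0.52 and Rnd3 0.52. Over all cells Eomes was at 0.83, Rpl32 at 1.10 and Rnd3 at -0.64 in this comparison. Kir-Gfp against E15.5 gave G1/S 0.34 and G2/M 0.45, with Rab11b 0.092, Neurod6 -0.37 and H2-D1 -0.26 reversed. Over all cells Neurod6 was at 0.98 and H2-D1 at 0.75 in this comparison. The shared-cell correlation of the Kir-Gfp and E15.5 differences from E14.5 was 0.427, but with separate E14.5 cells it was -0.0091 and -0.029. Within neuron-like cells, E15.5 against E14.5 reversed to G1/S 0.023, G2/M 0.010, Rplp1 0.18, Neurod6 0.25 and Dcx -0.34. Within unnamed cells its G1/S median was -0.15. With classes weighted equally, mitochondrially encoded reversed to 0.0074 for Kir-Gfp against E14.5, Nfix to -0.037 and Hsp90ab1 to -0.023 for E15.5 against E14.5, and Dcx to 0.068 for Kir-Gfp against E15.5. With list members of at least 50 RPM, E15.5 against E14.5 gave G1/S -0.17 and G2/M 0.0041, reversed. Interferon was then 0.64 for Kir-Gfp against E14.5, and G1/S 0.31 and interferon 0.65 for Kir-Gfp against E15.5. Without cells ranked neuron, Kir-Gfp against E14.5 reversed to migration 0.011, Fabp7 -0.052 and Nrp1 0.015. The G2/M median for E15.5 against E14.5 was -0.18 after centring and -0.013 in female cells.

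The apical progenitor-like share of E15.5 cells was 28.4% at Leiden resolutions 0.5 and 1.5, 38.1% with cells of at least 1000 genes and 50000 reads, and 30.2% with clustering within each group, which named no such cluster in the other groups. Leaving out each title number in turn gave 11.2% to 34.3% for E14.5 cells and 11.1% to 37.1% for E15.5 cells, so the shares depend on which cells are clustered. The same gave -0.14 to 0.030 for the mitochondrially encoded median of Kir-Gfp against E14.5, and -0.13 to 0.93 for Ldha in Kir-Gfp against E15.5, the lowest without title number 4. Leaving out 1 title number moved the G1/S median of E15.5 against E14.5 between -0.10 (title number 12) and -0.021 (title number 14). Male cells gave no value, since only the E15.5 group had cells typed male, and basal progenitor-like cells were too few in 2 groups. The late apical progenitor median of E15.5 against E14.5 kept its sign in every alternative run. Of all values 86.2% were 0 reads, and how depth acts on genes of different levels was not tested.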

Other observations

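The tests of depth and of plate or embryos for the late apical progenitor list, the test without cells ranked neuron, and all tests of pseudogenes and of positions, were chosen only after the result was seen, as was the repeat of the thinning with 20 seeds.

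The higher late apical progenitor list at E15.5 against E14.5 (median 0.42) was set against 3 technical explanations. After thinning to 208969 reads, which left out 19 E14.5 and 9 E15.5 cells with fewer, the median was 0.39, above the random range of -0.09 to 0.23, and in 20 of 20 thinnings it lay above its range, between 0.37 and 0.40, which argues against depth. Within apical progenitor-like cells it was 0.43, above the range of -0.36 to 0.25, which argues against a larger share of such cells as the whole cause. Title numbers shared by both groups were 0, so capture plate, embryos and age cannot be told apart, nor can electroporation and the 12 h delay to labelling, which are stated for E15.5 but not for E14.5 FlashTag cells. A progression of progenitors with age, which the design names, may be the reason and stays open beside these.

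The lower neuron migration and axon guidance list in Kir-Gfp against E14.5 cells (median -0.15) was weighed in the same way. Compared within title numbers the median was -0.12, below the range that begins at -0.09, which argues against uneven spread over title numbers. Without the neuron-like cluster it was -0.16, below -0.085, but that cluster misses most cells that rank as neurons by their markers. Without those the median was 0.011, inside its range, so fewer neurons in the Kir-Gfp group stay open. Nrp1 and Dcx belong both to the list and to the markers of that ranking, so part of this change may be built in. After thinning the list median was -0.087 against a range that begins at -0.081, and 19 of 20 thinnings lay below their range. That first thinned value met the bound set for it beforehand, but by less than its spread of -0.12 to -0.079 between thinnings, so depth stays open. Within apical progenitor-like cells the median was -0.024 (percentile 31.9), from 11 and 18 cells, and an effect of Kir2.1 itself was not tested, since each group is 1 sample.

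Some pseudogenes set E15.5 cells apart from both E14.5 groups, and they were left out of the ranking. Rps19-ps6 was at -2.78 for E15.5 against E14.5 while its parent Rps19 was at -0.42, which argues against expression of the parent gene, and Rpsa-ps10 was at 1.82. Rps19-ps6 reached 50 RPM in 72 E14.5 FlashTag cells (68.6%) and 41 Kir-Gfp cells (77.4%) but in 0 E15.5 cells, which allows up to 1.85% and argues against a variant carried by only some E15.5 embryos. Over 168 predicted genes and pseudogenes, without those that first showed the pattern, the SD of the E15.5 differences was 1.20 times that of the Kir-Gfp differences (0.80 for 3581 other genes), but the interquartile range 0.83 times (0.80). So a different read length, alignment or plate for the E15.5 libraries is neither shown nor excluded, and a variant shared by all embryos of 1 age stays open too.

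E14.5 FlashTag and Kir-Gfp cells shared 0 positions, that is pairs of title number and position number, where independent draws would share 11.9. All titles begin with the same words and each is unique, so no position could occur in both groups. The count therefore cannot decide how the groups were captured. Both had their shallowest cells under title number 6. That both groups were captured on 1 plate and separated afterwards is a candidate explanation that was not tested.

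A read of the Y-linked genes Ddx3y or Eif2s3y was found in 0 E14.5 FlashTag and Kir-Gfp cells together, which allows a share of up to 1.90%, and in 33 E15.5 cells (20.4%, 14.46 to 27.40). The Y-linked Kdm5d had a read in 3, 11 and 1 and Uty in 1, 12 and 2 cells of E14.5 FlashTag, E15.5 FlashTag and Kir-Gfp. Xist and the summed Y-linked genes each reached 10 RPM in the same cell in 2, 10 and 2 cells, and whether Y-linked genes were filtered differently between the files was not tested. By Xist against Y-linked genes, 63 E14.5 FlashTag, 65 E15.5 FlashTag and 37 Kir-Gfp cells were typed female, 14 E15.5 cells were typed male, and the others were untyped. Xist had a mean of 7.70, 6.26 and 8.47 in the order E14.5 FlashTag, E15.5 FlashTag and Kir-Gfp. The mitochondrial share of reads had medians of 2.73%, 2.63% and 2.74% in that order.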
